A study of Mus musculus with 24 samples.

How the data were processed

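Total RNA of BALB/3T3 clone A31 fibroblasts was extracted with Trizol and RNeasy columns and labelled as biotin cRNA with a TotalPrep kit, per the labels' protocols, and measured on 24 Illumina mouse bead arrays in 4 groups of 6 after 24 h. Per the file headers, the deposited non-normalized probe table holds 1 intensity per probe (45281 probes) with no normalisation, and its values are linear. The deposited non-normalized gene table holds intensity per gene symbol, which was checked to be the mean of the probe intensities. Per the file headers, the authors' normalized probe table holds log2 values, equal to the deposited series matrix, and the authors' normalized gene table holds log2 values per symbol. The submitters' processing notes name lumi and RMA, with no version and no role for either.

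The main values were computed from the non-normalized probe intensities with limma 3.58.1 in R 4.3.3, with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 for reading, matching and plotting. The file headers say that detection p-values should be included, but the files hold none and no control probes, so the planned detection filter was replaced: background correction used normexp with an offset of 50, then quantile normalisation. A probe counted as above background on an array when its log2 intensity exceeded the mode of that array plus the normal quantile that leaves 1% above it, scaled by the spread below the mode. Probes above background on at least 6 of 24 arrays were kept (20018), and 1 probe per gene, that with the highest mean, gave 13162 genes. Median probe intensity per array was 61.6 to 75.3, with 35.9% to 43.2% of probes above background.

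The probe identifiers of the non-normalized and normalized tables were matched within a symbol by their ranks over the arrays, and 34885 probes had 1 annotated gene. A further 18 probes with several genes were left out, and 10378 were not listed in the annotation and kept the array's own symbol. Current symbols came from the RefSeq table of assembly GRCm38.p6, used for names alone. Genes named only by the array's own symbol (2756 of 13162) were tested and counted but are not named here, and 3 of them were passed over among the largest changes.

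All 24 arrays entered 1 linear model with 1 mean per group (limma lmFit and eBayes, two-sided), with 6 comparisons and Benjamini-Hochberg adjustment within each at 0.05, so the groups share 1 spread estimate per gene. No batch is in the labels. Of 29 gene lists written before the data were examined, 27 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, adjusted over lists; an estimated correlation and fry were alternatives. Genes to name were set by a rule written before the data were examined: the 8 largest rises and falls against control (4 between metals) among called genes whose groups do not overlap, leaving out clone and locus names, a fixed set of metal, stress and growth genes, and members of called lists by smallest adjusted p. Of the last kind the text gives 2 per list past the test and none for the comparisons with iron. These limits were set after the values were seen, in place of a first choice among the rule's genes that was made by hand after seeing them and dropped.

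The steps were tested on simulated data with 200 changed genes per comparison. In the simulated iron comparison (13697 genes) 2% of genes changed 1.2-fold, 58% of genes changed 1.5-fold, 78% changed 2-fold and 96% changed 4-fold were called, and 0.007% of unchanged genes. In the simulated manganese comparison the shares were 2%, 42.9%, 91.8%, 96% and 0.007%. In the simulated alloy comparison, where the alloy's own larger spread was simulated, 20.8%, 72%, 90% and 98% of changed genes were called, but so were 245 of 13462 unchanged genes (1.82%); with the 2 groups alone 16 were (0.119%). The limit of 1% written before this test was run was not met by the shared model for the alloy; the limit was then applied to the fit of 2 groups, and the shared model was kept with the counts of the 2-group fit beside it.

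Alternatives were the other deposited tables, median scaling, no normalisation, cyclic loess, no background correction, other filters and probe choices, minimum folds of 1.5 and 2, limma treat against a 1.2-fold minimum, the replicate number as a block, array weights, only the 2 groups compared, and leaving out each array in turn. Added after seeing the data were an offset of 16, all arrays but the 6 alloy arrays, and leaving out alloy replicates 1, 3 and 4. Overlaps between comparisons that share controls were recomputed with separate sets of 3 controls. Gene lengths and coordinates were not used, as no genome build is named in the files.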

Results

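Gene expression was measured in BALB/3T3 clone A31 cells, a fibroblast line from mouse embryo, after 24 h of culture beneath metal powder held in tissue culture inserts. The 24 Illumina mouse bead arrays fell into 4 groups of 6: no metal (control), pure iron, pure manganese at 0.5 mg/ml and an iron-manganese alloy (Fe-35Mn) at 5 mg/ml. If the 35 in the alloy's name is a mass percent, its dose held as much iron as the dose of pure iron and 1.75 mg/ml manganese, 3.5 times the dose of pure manganese. The titles call the 6 replicates technical and the protocol speaks of at least 6 replicates per metal, so the p-values measure the spread between these arrays, which may be technical. The median probe intensity per array was 61.6 to 75.3, and 35.9% to 43.2% of probes lay above the array's background. The number of arrays limits the precision.

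The first principal component held 75.8% of the variance. The control arrays had a mean score of -25.7 (SD 0.11, n = 6) and the iron arrays of -25.3 (SD 0.56, n = 6), while the manganese arrays averaged 24.1 (SD 1.57, n = 6) and the alloy arrays 26.9 (SD 14.6, n = 6). The alloy arrays ran from 9.48 to 48.5, and the median SD of a gene was 0.147 log2 units in the alloy group against 0.0761 in the control, 0.0766 in the iron and 0.0834 in the manganese group.

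**Figure D1:**
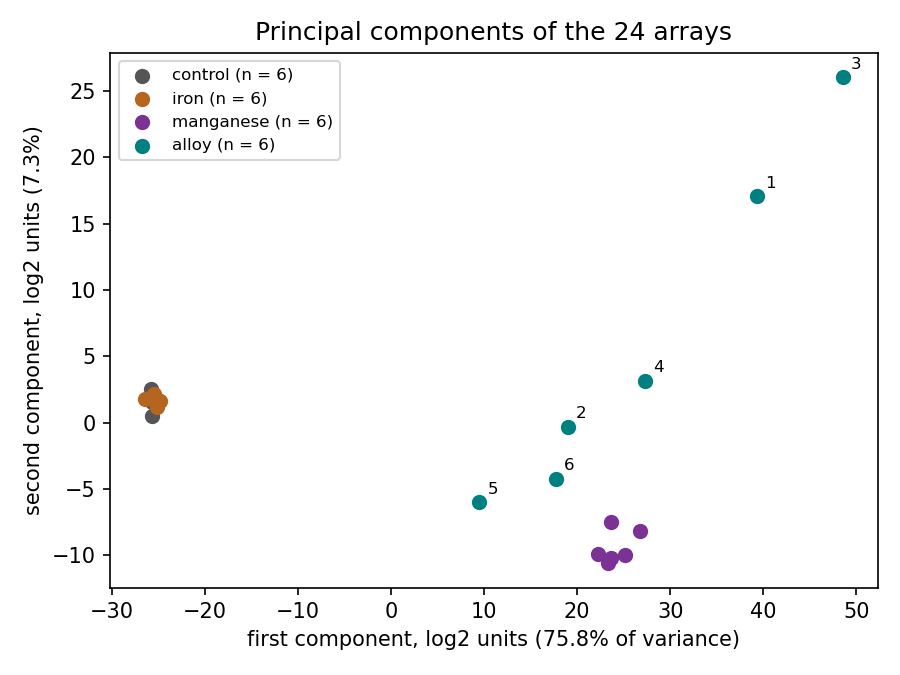
Scores of the 24 arrays on the first and the second principal component of log2 expression, 1 point per array, with the 6 alloy arrays numbered by replicate. Control and iron arrays lie together near -25.7 and -25.3 on the first component, and the alloy arrays spread from 9.48 to 48.5.

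Pure iron was compared with no metal to find the transcripts that differ in fibroblasts under iron powder. Tfrc, which encodes the transferrin receptor for iron uptake, was 1.82-fold lower with iron (log2 change -0.86, SE 0.0873, adjusted p = 5.43e-06, n = 6 per group). Each of the 6 iron arrays lay below all controls. Kat6a, a histone acetyltransferase, was 1.46-fold lower (log2 change -0.55, SE 0.0618, adjusted p = 2.31e-05). Syne2, a nuclear envelope protein, was 1.49-fold lower (log2 change -0.58, SE 0.102, adjusted p = 0.00939). Smaller falls were those of Papola (-0.38), Rai1 (-0.38), Tab2 (-0.37), Xist (-0.35) and Cacna2d1 (-0.32). In the model of all 24 arrays the mitochondrial transporter Sfxn4 was the single gene past the threshold that rose (log2 change 0.23, SE 0.0507, adjusted p = 0.0425). The ferritin chains Fth1 and Ftl1 differed by -0.03 and 0.11, the iron exporter Slc40a1 by 0.02, the haem oxygenase Hmox1 by 0.21, the metallothionein Mt1 by -0.06 and Vegfa by 0.02, none past the threshold. Hmox1 passed with only the 2 groups fitted (adjusted p = 0.0216). Not past either were Nqo1 (0.08), Cdkn1a (0.07), Sod2 (-0.04) and the zinc or manganese transporters Slc30a1 (-0.09) and Slc39a14 (-0.09).

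In all, 32 of 13162 genes passed an adjusted p of 0.05 with iron, 1 higher and 31 lower, none by 2-fold, and 1118 had an unadjusted p under 0.05. The 6 iron arrays did not overlap the 6 controls for 2.12% of genes, against 0.216% by chance. Of the genes with no overlap 110 were higher and 169 lower with iron. Of the 27 gene lists, 0 passed by camera, and fry called 0 in 1 direction. The lowest camera adjusted p was 0.209, for inflammatory chemokines and NF-kB targets (0 of 29 members past the threshold, also 0 adjusted over the list alone), and this list passed in 4 alternatives, with 0.00531 for only the 2 groups. Among iron uptake, storage and export genes 1 of 21 fell, which was Tfrc, and 1 adjusted over the list alone; the mixed fry test, for changes in either direction, gave this list an adjusted p of 0.00286. Median, mean and camera direction differed in sign for heat shock proteins, p53 targets, endoplasmic reticulum chaperones and myogenic markers. The count depended on the fit: it was 3 with median scaling, 2 with no normalisation between arrays and 311 with only the 2 groups fitted. Sfxn4, Papola, Rai1, Tab2, Xist and Cacna2d1 lost the threshold with either of the first 2, and Syne2 with no normalisation (adjusted p = 0.0804). Sfxn4, Papola, Xist and Cacna2d1 also lost it without single arrays, and Rai1 (-0.12) and Xist (-0.25) as the mean of their probes. Leaving out 1 array gave 10, 20 and 11 without control replicates 2, 3 and 4, 16, 18 and 15 without iron replicates 3, 5 and 6, and 67 without alloy replicate 3. The shared spread estimate includes the alloy arrays, where the median SD of a gene was 0.147 against 0.0766 in iron arrays. On simulated data the fit of the 2 groups called 147 of 200 genes changed with iron and 0.104% of unchanged ones. The 32 is the count of 1 fit and does not measure the size of the iron response. Syne2 was -0.03 and 0.00 in the authors' gene tables, and Tfrc was -0.46 and Kat6a -0.09 in their normalized probe table.

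Pure manganese was compared with no metal. The largest rises included the interferon-stimulated genes Ifi207 (15.4-fold, log2 change 3.94, SE 0.246, n = 6 per group), Rsad2 (3.89, SE 0.400), Oas2 (3.37, SE 0.186) and Ifit3 (3.32, SE 0.215). The chemokines Cxcl10 (3.69, SE 0.406) and Ccl5 (3.39, SE 0.373) rose as well, though the list of inflammatory chemokines went both ways, 11 of 29 rising and 12 falling. Dusp4, a phosphatase of MAP kinases, rose 12.6-fold (3.66, SE 0.160). The actin-binding Avil rose by 3.81 (SE 0.285), with control signal above background on 2 of 6 arrays, and by 1.36 in the authors' normalized probe table. The largest falls were Depp1 (9.53-fold, -3.25, SE 0.132), the chemokine Cxcl12 (-2.85, SE 0.259), Mxd4 (-2.47), the activin antagonist Fst (-2.46), the growth factor Fgf7 (-2.36), Tcf7l1 (-2.25), Nrep (-2.15) and the matrix protein Prelp (-2.09). Each of these genes had adjusted p of 4.68e-08 or lower and 6 of 6 manganese arrays beyond all controls. Fold sizes depended on the processing: in the authors' normalized gene table Dusp4 was 1.83, Cxcl10 1.63, Vegfa 1.46 and Slc7a11 0.60, and the hypoxia median was 0.42 in their normalized probe table.

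Iron and metal genes went both ways with manganese. Tfrc rose 3.26-fold (1.70, SE 0.0873), opposite to its fall with iron, and Hmox1 rose 5.08-fold (2.35, SE 0.275), while Mt1 fell 1.78-fold (-0.83, SE 0.0604). Fth1 rose by 0.14 (adjusted p = 0.0111, but 0.270 with cyclic loess), and Ftl1 (0.09), Slc39a14 (0.05) and Sod2 (-0.04) did not pass. Slc30a1 fell by 0.29, Cdkn1a rose by 1.01 and Nqo1 by 0.66. Slc40a1 was -0.29 on its chosen probe, but its other probe was 0.64 and the mean of its probes 0.18, so no direction is given for it.

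Among the lists, all 37 measured genes of the integrated stress response rose with manganese (median log2 change 1.13, camera adjusted p = 9.1e-24), with Trib3 (2.41) and Chac1 (2.19) smallest in adjusted p. Cholesterol biosynthesis and uptake genes fell, 22 of 23 (median -0.99, adjusted p = 5.15e-18), with Mvd at -2.03 and Lss at -1.49. Hypoxia response genes rose, 20 of 23 with 2 falling (median 0.86, adjusted p = 3.21e-09), with Vegfa at 2.63, Ak4 at 1.82 and the glucose transporter Slc2a1 at 1.70. Glycolysis genes rose, 13 of 16 (0.51, adjusted p = 3.21e-07), with Pfkl at 1.52. Ribosome biogenesis genes rose, 24 of 31 (0.48, adjusted p = 1.87e-09), with Rrp12 at 1.02 and Mrto4 at 0.82. Immediate early genes rose, 14 of 22 with 4 falling (0.56, adjusted p = 0.00379), though Klf2 in that list fell by 1.57. Contractile genes and targets of the transcription factor SRF fell, 16 of 22 with 2 rising (-0.56, adjusted p = 3.35e-06), with Cald1 at -1.47 and Tpm1 at -1.05.

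Calls of 4 further lists with manganese were lost with an estimated correlation between genes, while those of the 7 above held. This correlation was estimated over all 24 arrays, so it includes the spread of the alloy arrays. For interferon-stimulated genes the SD of the list mean was 0.558 in alloy and 0.0347 in manganese arrays, and for mitosis genes 0.323 and 0.0302. The interferon list mean was 1.45 to 1.55 in manganese arrays and -0.09 to 0.08 in controls. Interferon-stimulated genes rose, 29 of 32 with 2 falling (median 1.38, adjusted p = 9.71e-13; adjusted p = 0.255 with an estimated correlation), and Ifi27 in that list was 3.99-fold lower. NRF2 targets, genes of the oxidative stress response, rose, 24 of 32 with 4 falling (0.39, adjusted p = 5.8e-06; adjusted p = 0.255 with an estimated correlation), with Slc7a11 at 3.20 and Mafg at 1.19. Extracellular matrix genes fell, 22 of 35 with 2 rising (-0.37, adjusted p = 6.76e-06; adjusted p = 0.056 with an estimated correlation), with Ogn at -1.96 and Mgp at -1.55. Mitosis genes fell, 17 of 31 with 1 rising (-0.26, adjusted p = 0.00932; adjusted p = 0.707 with an estimated correlation), with Kif11 at -0.71 and Mad2l1 at -0.60. Adjusted over the list alone, these counts were the same except that 15 immediate early genes rose and 1 glycolysis gene fell. Median, mean and camera direction differed in sign for inflammatory chemokines, endoplasmic reticulum chaperones, heat shock proteins and DNA replication genes, whose calls did not pass. Lists share members: Slc7a11 is in the stress response and NRF2 lists, Atf3 in the stress response and immediate early lists, Slc2a1 and 2 more in the hypoxia and glycolysis lists and Sqstm1 in the NRF2 and lysosome lists. Of 13162 genes 7205 passed, 3472 higher and 3733 lower, with 318 and 207 by at least 2-fold. In all, 42.8% of genes had no overlap between groups, against 0.216% by chance.

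The alloy was compared with no metal. The largest rises were Avil (17.0-fold, log2 change 4.08, SE 0.285, n = 6 per group), Rsad2 (3.95, SE 0.400), the chemokines Ccl5 (3.92, SE 0.373) and Cxcl10 (3.51, SE 0.406), Dusp4 (3.87, SE 0.160), the keratin Krt16 (3.56, SE 0.275) and the stress transcription factor Atf3 (3.50, SE 0.324). Control signal lay above background on 2, 2 and 3 of 6 arrays for Avil, Krt16 and Atf3. In the authors' normalized gene table Dusp4 was 2.07, Cxcl10 1.64, Vegfa 1.35 and Slc7a11 0.70, and in their normalized probe table Avil was 1.64. The chemokine Ccl4, below background on all control arrays, was at least 11.1-fold higher. The largest falls were Cxcl12 (11.8-fold, -3.57, SE 0.259), Depp1 (-3.42, SE 0.132, alloy signal above background on 4 of 6 arrays), Mxd4 (-2.84), the secreted matrix regulator Ccn2 (-2.80), Fgf7 (-2.63), Prelp (-2.60), Eva1b (-2.53) and the glutamate transporter Slc1a3 (-2.51). Hmox1 rose 10.3-fold (3.37, SE 0.275), Tfrc 1.70-fold (0.77, SE 0.0873), Nqo1 2.13-fold (1.09), Ftl1 by 0.58 and Fth1 1.18-fold (0.23), while Mt1 was 1.31-fold lower (-0.39) and Slc30a1 was lower by 0.26. The log2 level of Hmox1 ran from 11.2 to 13.93 over the alloy arrays and from 9.08 to 9.36 over the controls. Its SE comes from the spread shared by the 4 groups and does not measure the alloy spread. Cdkn1a rose by 0.73, and Slc39a14 (0.09), Sod2 (0.13) and Slc40a1 (-0.03 on its chosen probe) did not pass. Slc40a1 was 1.41 on its other probe. It passed as higher in the authors' 2 gene tables and as the mean of its probes, so no direction is given for it. Sod2 passed at 0.20 without alloy replicate 4 (adjusted p = 0.0117), and Slc39a14 at 0.16 in the authors' non-normalized gene table (0.00827) and as the mean of its probes (0.00927).

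With the alloy, 36 of 37 integrated stress response genes rose (median log2 change 1.21, camera adjusted p = 1.42e-24), with Trib3 at 2.55 and Chac1 at 2.10. In the cholesterol list 22 of 23 cholesterol genes fell (-0.78, adjusted p = 5.91e-14), with Mvd at -1.92 and Lss at -1.29. Ribosome biogenesis genes rose, 27 of 31 (0.55, adjusted p = 6.95e-11), with Rrp12 at 1.01 and Mrto4 at 0.91. Hypoxia response genes rose, 17 of 23 with 2 falling (0.40, adjusted p = 1.72e-05), with Vegfa at 2.50, Slc2a1 at 1.40 and Ak4 at 1.35. Glycolysis genes rose, 13 of 16 with 1 falling (0.34, adjusted p = 3.81e-05), with Aldoa at 0.72. Extracellular matrix genes fell, 25 of 35 with 2 rising (-0.56, adjusted p = 5.29e-07), with Ogn at -2.11 and Mgp at -1.59. Contractile and SRF target genes fell too, 16 of 22 with 3 rising (-0.52, adjusted p = 7.94e-05), with Cald1 at -1.28 and Tpm1 at -0.92. These 7 calls held with an estimated correlation.

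NRF2 targets rose with the alloy, 28 of 32 with 3 falling (0.68, adjusted p = 5.53e-11; adjusted p = 0.0661 with an estimated correlation), with Slc7a11 at 3.37 and Mafg at 1.40. Interferon-stimulated genes rose, 26 of 32 with 2 falling (1.00, adjusted p = 1.99e-08; adjusted p = 0.421 with an estimated correlation), with Usp18 at 2.69 and Irf9 at 0.94. Immediate early genes rose, 13 of 22 with 5 falling (0.57, adjusted p = 0.00506; adjusted p = 0.0522 with an estimated correlation), Klf2 falling by 1.74. Lysosome and autophagy genes rose, 19 of 37 with 5 falling (0.24, adjusted p = 0.00361; adjusted p = 0.634 with an estimated correlation), with Sqstm1 at 1.84 and Ctsl at 1.09. Mitosis genes fell, 18 of 31 (-0.34, adjusted p = 0.00361; adjusted p = 0.641 with an estimated correlation), with Cdca3 at -0.74 and Mad2l1 at -0.56. Without alloy replicates 1, 3 and 4, chosen after seeing the principal components and the brightness, the medians of the last 2 lists were 0.04 and -0.07 and neither call held. Adjusted over the list alone, counts differed by at most 2 members. Signs of median, mean and camera direction differed for inflammatory chemokines, osteochondral markers and respiratory chain genes.

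Of 13162 genes 7437 passed with the alloy, 3560 higher and 3877 lower, with 312 and 275 by at least 2-fold. No overlap was seen for 33.3% of genes, against 0.216% by chance. The shared spread estimate is too small for the alloy group: on simulated data it called 1.82% of unchanged genes in this comparison, and the fit of the 2 groups alone gave 6548. The balance of directions depended on the scaling, with 1966 higher and 4655 lower after median scaling and 1485 and 4995 with no normalisation, where the median of all genes shifted by -0.13.

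**Figure D2:**
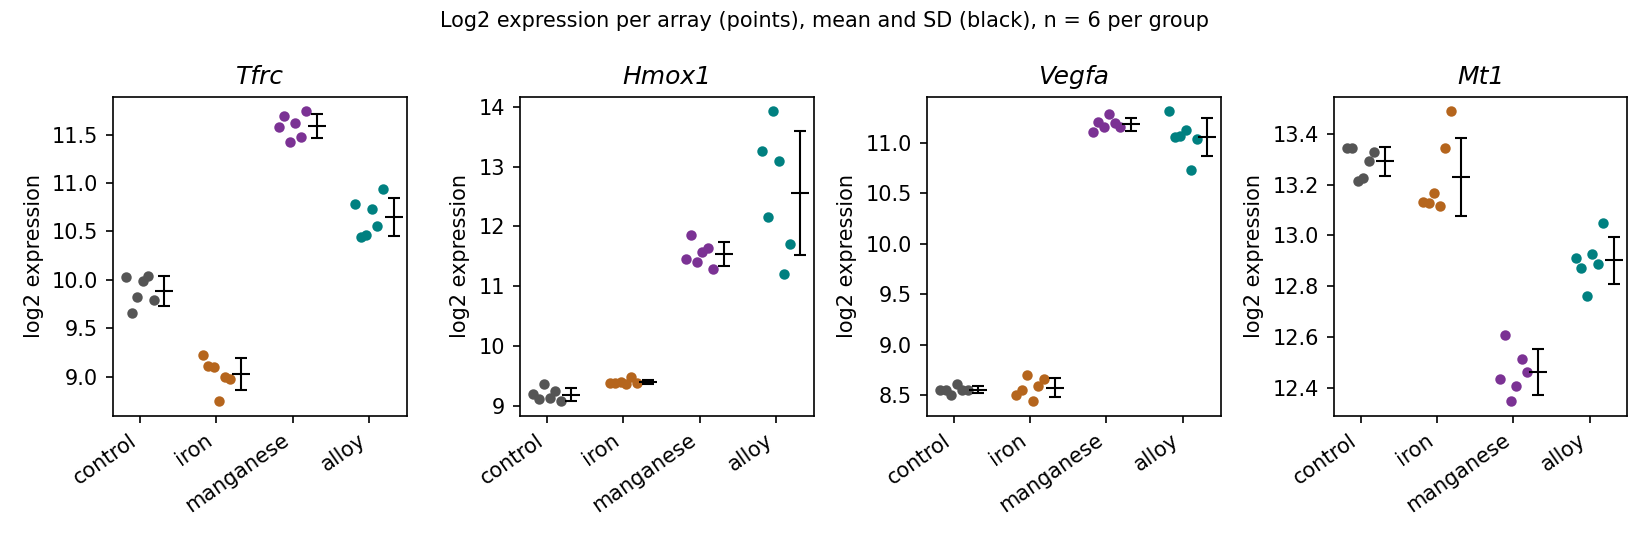
Log2 expression of Tfrc, Hmox1, Vegfa and Mt1 in each of the 24 arrays (points), with the mean and SD of each group in black (n = 6). Tfrc lies 0.86 below control with iron and 1.70 above it with manganese, and Hmox1 lies 3.37 above control with the alloy.

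Alloy and manganese calls overlapped. Of the genes called in both, 5905 changed in the same direction, 2841 higher and 3064 lower, and 25 in opposite directions, against 939.1 and 1099.6 if the lists were independent. Because both comparisons share the controls, they were recomputed with separate sets of 3 controls, which gave 4822 to 4972 shared genes over 20 splits. Of the 32 genes called with iron, 24 were called lower with manganese too (8.8 if the lists were independent, 1 to 15 with split controls) and 21 lower with the alloy (9.1 if independent, 1 to 11 with split controls). The number of genes called with iron in each split is not given, and leaving out single control arrays could shorten that list. The split counts for iron thus cannot show how far the sharing rests on the shared controls. Across genes the log2 changes with manganese and with the alloy had a Pearson r of 0.934. It was 0.912 to 0.931 with split controls and averaged 0.252 in simulations without change, and genes are not independent replicates.

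Alloy and manganese were compared directly, at doses of 5 and 0.5 mg/ml that differ. Ifi27, which fell with manganese, was 2.61-fold higher with the alloy (log2 difference 1.38, SE 0.0741, n = 6 per group), and Kitl (1.12, SE 0.174), the mitochondrial regulator Ppargc1a (0.91, SE 0.148) and Crebbp (0.87, SE 0.151) were higher as well. Oas2 (2.94-fold lower, -1.56, SE 0.186), Hap1 (-1.27, SE 0.0760), the carbonic anhydrase Car9 (-0.96, SE 0.162) and Ly6e (-0.95, SE 0.0925) were lower, and so was Tfrc (1.92-fold lower, -0.94, SE 0.0873). Ftl1 (0.50), Mt1 (0.44), Nqo1 (0.43) and Slc40a1 (0.26, on its chosen probe) were higher and Cdkn1a lower (-0.27). Fth1 (0.10), Vegfa (-0.13), Sod2 (0.17), Slc30a1 (0.02) and Slc39a14 (0.04) did not pass. Of these, Fth1 passed at 0.17 in the authors' normalized probe table (adjusted p = 0.0201), Vegfa at -0.24 without alloy replicates 1, 3 and 4 (0.00823) and with array weights (0.0392), and Sod2 without alloy replicate 4 (0.016). Hmox1 was higher by 1.02 (adjusted p = 0.0137), but with the 2 groups alone adjusted p was 0.132, and without alloy replicates 1, 3 and 4 the difference was 0.16.

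In this comparison hypoxia response genes were lower, 14 of 23 (median -0.25, camera adjusted p = 1.11e-07), with Ak4 at -0.47 and 15 adjusted over the list alone. Cholesterol genes were higher, 11 of 23 (0.16, adjusted p = 1.92e-07), with Insig1 at 0.47 and Fdps at 0.37; the hypoxia and cholesterol calls held with an estimated correlation. NRF2 targets were higher, 14 of 32 (0.31, adjusted p = 3.54e-13; adjusted p = 0.0797 with an estimated correlation), with Txn1 at 0.65, and 23 higher and 1 lower adjusted over the list alone. Interferon-stimulated genes were lower, 12 of 32 with 1 higher (-0.44, adjusted p = 5.87e-07; adjusted p = 0.489 with an estimated correlation and 0.0875 by fry), with Psmb8 at -0.74, and 16 lower adjusted over the list alone. The alloy arrays differed in the mean of this list: replicate 3 stood at 2.07, replicate 1 within the range of the manganese arrays (1.45 to 1.55) and the other 4 at 0.67 to 1.02. Without alloy replicates 1, 3 and 4 the median was -0.89. Glycolysis genes were lower, 5 of 16 (-0.13, adjusted p = 0.000218; adjusted p = 0.0797 with an estimated correlation), with Pfkl at -0.49 and Tpi1 at -0.34, and 7 adjusted over the list alone. Respiratory chain genes were higher, 8 of 41 (0.09, adjusted p = 0.000259; adjusted p = 0.143 with an estimated correlation), with Ndufb9 at 0.43 and Atp5d at 0.25, and 9 adjusted over the list alone.

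Between alloy and manganese 5 more lists passed with few members past the threshold singly, and fry did not call the lysosome, chaperone and stress response lists. Camera tests whether the members as a set differ from all other genes, and their own shift was small, with medians of 0.05 to 0.10. Of 16 alternatives 10 changed the stress response call below, 8 the metallothionein call, 5 the contractile call, 2 the chaperone call and 1 the lysosome call. Without alloy replicate 3 alone the lysosome and chaperone medians were 0.03 and 0.02 and neither call held (adjusted p = 0.202 and 0.467), and of 24 runs without 1 array 6, 6 and 3 changed the stress response, metallothionein and contractile calls. Extracellular matrix genes, at an adjusted p of 0.0506, passed as lower in 7 of 16 alternatives. Camera adjusted p was 0.0032 for lysosome and autophagy genes (3 of 37 higher; adjusted p = 0.494 with an estimated correlation), 0.0199 for endoplasmic reticulum chaperones (2 of 23; adjusted p = 0.489 with an estimated correlation) and 0.0319 for contractile genes (2 of 22 higher, 1 lower, 3 and 1 adjusted over the list alone; adjusted p = 0.268 with an estimated correlation). It was 0.0465 for the integrated stress response (1 of 37, Sesn2 at 0.49; adjusted p = 0.68 with an estimated correlation) and for metallothioneins and zinc or manganese transport (2 of 17, 5 higher and 2 lower adjusted over the list alone; adjusted p = 0.375 with an estimated correlation). Members named by the rule were Atp6v1a (0.54), Map1lc3b (0.48), Sec61b (0.31), Dnajc3 (0.14), Acta2 (0.18), Ccn2 (-0.94) and Slc39a10 (0.23). With the 2 groups alone Sec61b, Dnajc3, Acta2, Ccn2, Slc39a10, Slc40a1 and Cdkn1a did not pass. Without alloy replicates 1, 3 and 4 the medians of the lysosome, chaperone and stress response lists turned to -0.09, -0.06 and -0.09. Signs of median, mean and camera direction differed for myogenic, osteochondral and epithelial markers, immediate early genes and matrix proteases. Of 13162 genes 2013 passed, 836 higher and 1177 lower, 3 and 7 by at least 2-fold. The 2 groups alone gave 559, median scaling 1072 and no normalisation 847. In all, 3.56% of genes had no overlap, against 0.216% by chance.

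**Figure D3:**
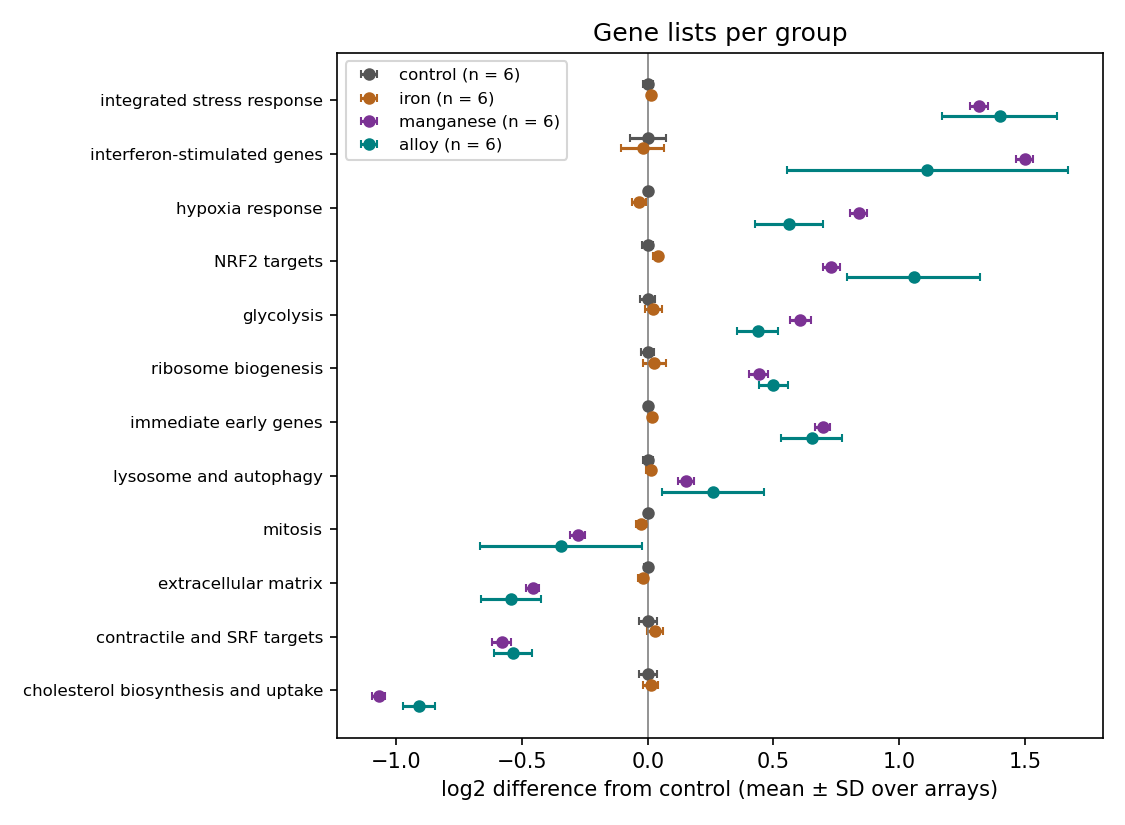
Mean log2 difference from the control mean over the members of 12 gene lists, as the mean and SD over the 6 arrays of each group. Integrated stress response genes average 1.32 with manganese and 1.40 with the alloy, and iron lies near 0 for each list shown.

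Alloy and manganese were each compared with iron too. Against iron, manganese changed 7125 of 13162 genes, 3447 higher and 3678 lower, and the alloy 7449, 3543 higher and 3906 lower. Rsad2 (3.99 and 4.05) and Avil (13.2-fold and 16-fold) were among the largest rises for manganese and the alloy, with Ifi207 (3.89) and Dusp4 (3.64) for manganese and Ccl5 (3.90) and Ccl4 (at least 11.2-fold) for the alloy. Depp1 (-3.32 and -3.48), Cxcl12 (-2.78 and -3.49) and Mxd4 (-2.37 and -2.75) fell in both, with Fst (-2.45) for manganese and Ccn2 (-2.72) for the alloy. Iron signal of Avil lay above background on 5 of 6 arrays. Tfrc was 5.92-fold higher with manganese than with iron (2.57, SE 0.0873, n = 6 per group) and 3.09-fold higher with the alloy (1.63). Hmox1 was higher by 2.14 and 3.16, Vegfa by 2.61 and 2.48, Nqo1 by 0.58 and 1.01, Cdkn1a by 0.94 and 0.67 and Fth1 by 0.17 and 0.27. Mt1 was lower (-0.77 and -0.33), and so was Slc30a1 (-0.20 and -0.18). Ftl1 was higher with the alloy alone (0.47; -0.02 with manganese, a difference of 0.50 when tested). Slc39a14 passed (0.13, adjusted p = 0.046, and 0.18, adjusted p = 0.00834), but both calls were lost with median scaling and no normalisation, the first also in the authors' tables. Sod2 did not pass (0.00 and 0.17), but for the alloy adjusted p was 0.00276 without alloy replicate 4. Slc40a1 was -0.31 and -0.04 on its chosen probe and 0.12 and 0.64 as the mean of its probes. Camera called 11 lists for manganese and 12 for the alloy, of which 6 and 7 held with an estimated correlation; the integrated stress response had the smallest adjusted p in both (37 and 36 of 37 higher, adjusted p = 3.09e-24 and 1.05e-24).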

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

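The tests of array brightness, of a uniform scaling and of the sum of the Tfrc changes were chosen after the result was seen. So was the test without alloy replicates 1, 3 and 4, which were picked from the principal components and the brightness. Single arrays were compared with the other 5 of their group in 472 groups, of which 29 (6.1%) had 1 array far from the rest; chance gives about 1 in 20 groups.

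Alloy replicate 4 was dim: its median intensity was 61.58 (others 68.77 to 72.03), 35.92% of its probes lay above background (39.67% to 40.73%) and its mean rank correlation with its group was 0.9212 (0.9376 to 0.9423). Manganese replicate 1 had a median intensity of 74.57, and control replicate 1 a mean rank correlation of 0.9548. Among list scores, as mean log2 difference from control, alloy replicate 3 stood at 0.60 for endoplasmic reticulum chaperones and 0.54 for inflammatory chemokines, alloy replicate 5 at -0.04 for matrix proteases and -0.78 for cholesterol genes, alloy replicate 1 at 0.10 for respiratory chain genes, alloy replicate 4 at -0.10 for myogenic markers and iron replicate 1 at 0.04 for iron uptake genes. Single genes, by log2 level, were Papola (9.62), Nqo1 (8.63) and Sesn2 (8.94) in control replicate 2, Mxd4 (11.54) in control replicate 3 and Map1lc3b (9.11) in control replicate 1. In iron arrays they were Ccl5 (8.75, replicate 4), Chac1 (10.85, replicate 2), Ccn2 (13.28) and Fdps (13.03) in replicate 1. In manganese arrays they were Mgp (10.25, replicate 1), Mvd (8.10, replicate 6) and Klf2 (7.05, replicate 4). In alloy arrays they were Lss (9.80) and Aldoa (13.46) in replicate 4, Kitl (9.09) and Hap1 (8.46) in replicate 3 and Ndufb9 (9.22) in replicate 6.

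The alloy arrays lay further apart than the manganese arrays along the first component (SD 14.64 against 1.57). The dimmest array scored 27.27, between the others (9.48 to 48.52), so brightness alone did not order the 6 arrays, but this rests on 1 array. Over the other 5 the score had an r of -0.51 with the median intensity and -0.58 with its 75th percentile. Brightness thus stays open as a source. A differing extent of the manganese response stays open: 22.2% of the variance between alloy arrays (95% interval 20.4 to 24.1 over genes) lay along the manganese changes, under the 50% set beforehand, but that bound was wrong because it counts variance outside the first component. Slopes of the arrays on those changes (0.69, 0.83, 0.84, 0.97, 1.17 and 1.31) followed their order on that component, which itself lies mostly along the manganese changes (cosine 0.968), so this order decides nothing. Means of the hypoxia list ran against the slopes: 0.41 and 0.42 in replicates 3 and 1 (slopes 1.31 and 1.17), 0.69 and 0.71 in replicates 5 and 6 (0.69 and 0.83). Means of NRF2 targets ran with them: 1.38, 1.31, 0.68 and 0.89 in the same arrays. The hypoxia values argue against 1 extent for all genes, and for other lists a differing extent stays open. No other explanation was tested, as the labels give no difference between the arrays.

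With iron, 31 of 32 called genes fell. Whether the normalisation set this direction was not decided. With cyclic loess 33 of 37 genes fell (89.2%), but that method also aligns the arrays with each other. Median scaling and no normalisation called 3 and 2 genes, all lower, too few to test it. With no normalisation Syne2 (-0.62), Papola (-0.39), Rai1 (-0.40), Tab2 (-0.37), Xist (-0.36) and Cacna2d1 (-0.36) stayed lower but lost the threshold. A shared variation between arrays of 1 group may contribute: the deviations of the 31 genes within control and iron arrays had a mean pairwise r of 0.27, against a 95th percentile of 0.034 over 1000 random sets of like level. The 31 genes were lower in each metal group, with means of -0.38 (iron), -0.32 (manganese) and -0.23 (alloy) and a control range of -0.06 to 0.11. Singly, 24 were called lower and 2 higher with manganese, and 21 lower and 4 higher with the alloy. The genes were selected against these same controls. A difference of the control arrays, which the 3 comparisons share, was not tested and stays open. Iron itself stays open as an explanation too.

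Between alloy and manganese, NRF2 targets and cholesterol genes were higher and hypoxia and interferon genes lower, though with an estimated correlation the NRF2 (adjusted p = 0.0797) and interferon (0.489) calls were lost and only cholesterol and hypoxia held (0.025 each). A uniform scaling of the manganese response would move all genes that rose with manganese the same way. With the 2 groups alone, of 24 such NRF2 targets 4 were higher with the alloy and 0 lower, and of 20 such hypoxia genes 0 were higher and 5 lower, which argues against it. Alloy replicates 1, 3 and 4 were left out, and 4 of the 4 lists still passed by camera in the same direction. The arrays left out had the highest first-component scores (27.27 to 48.52, the others 9.48 to 18.96). List sizes changed: the NRF2, cholesterol, hypoxia and interferon medians were 0.13, 0.18, -0.12 and -0.89, against 0.31, 0.16, -0.25 and -0.44 with all arrays. In the interferon list the arrays left out had the highest means (1.02 to 2.07, the others 0.67 to 0.72). Its pass as lower was thus built in and shows nothing. In the NRF2 and hypoxia lists they lay furthest from manganese, and the smaller differences that remained passed. The metals' doses and composition differ together, so which of them matters was not tested.

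Other splits of the 12 arrays into groups of 6 were refitted with the 2 groups alone, 100 splits each with the real one included. In each comparison 1 of 100 splits, the real one, gave as many genes. For iron against control and alloy against manganese this argues against a grouping by chance. For manganese and the alloy, 42.8% and 33.3% of genes had no overlap with control. Against iron it was 42.27% and 33.45%, so these outcomes were fixed beforehand. The splits cannot tell a metal's effect from any other steady difference between the arrays of 2 groups, such as separate cultures or slides. The real and the highest other counts were 311 and 98 for iron against control, 8129 and 2899 for manganese, 6548 and 3266 for the alloy, 6562 and 3443 for alloy against iron, 559 and 16 for alloy against manganese and 8048 and 2880 for manganese against iron.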

How the results depend on the processing

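The offset of 16, the fit without the 6 alloy arrays and the fit without alloy replicates 1, 3 and 4 were chosen after the data were seen, the last on the principal components and brightness. The slide was not in the files, so the slide block was not run. The authors' array codes run in order by group. If each group filled its own slide, slide and metal could not be told apart, which no fit here tests. Of 6775 comparisons of called named genes with alternatives 6617 kept direction and side of the threshold, 152 lost the threshold and 6 reversed. Of 2302 for called lists 2253 kept both, 40 lost it and 9 reversed. Part of this agreement is built in. Leaving out an array of a group outside the comparison cannot change the fold, and the series matrix repeats the authors' normalized probe table. For iron against control (32 genes) the count was 3 with median scaling, 2 with no normalisation, 61 with the authors' normalized probe table and with the series matrix, 94 with their normalized gene table, 65 counted as probes, 311 with only the 2 groups, 54 with a replicate block (same-numbered arrays correlated over 0.1 in 4 of 6 pairs here and in 1 or 2 of 6 elsewhere, and of 6 metal arrays 3 here, 4 for manganese against control and 1 or 2 elsewhere matched best with their own number, so pairing was not taken as given), 538 with array weights, 227 without the alloy arrays and 218 without alloy replicates 1, 3 and 4; leaving out 1 array gave 10 to 67. Alloy against manganese (2013) gave 1072, 847 and 559 with median scaling, no normalisation and only the 2 groups, and 1473 to 2908 leaving out 1 array. Requiring at least 1.5-fold, at least 2-fold or treat at 1.2-fold keeps fewer genes by construction: 2, 0 and 1 for iron (1118 at unadjusted p under 0.05), 1605, 525 and 2491 for manganese, 1793, 587 and 2831 for the alloy, 1806, 576 and 2799 for alloy against iron, 96, 10 and 28 for alloy against manganese, 1576, 518 and 2462 for manganese against iron, and 1294, 422 and 2049 for the 5905 genes shared by manganese and alloy. Leaving out 1 array gave 6904 to 7522 genes for manganese, 7136 to 7645 for the alloy, 7172 to 7648 for alloy against iron, 6775 to 7448 for manganese against iron and 5654 to 6016 shared. The block changed these calls: Sod2 passed in alloy against iron (adjusted p = 0.045), extracellular matrix in alloy against manganese (0.0472) and respiratory chain in manganese against iron (0.0465), and metallothioneins in alloy against manganese did not (0.0521). Fold sizes of 80 of 168 called values of named genes moved by over 1.5 times, 70 of them in the authors' normalized values. Lists past the test: iron against control had 1 in place of 0 (inflammatory chemokines) with no normalisation, only the 2 groups, without the alloy arrays and without alloy replicates 1, 3 and 4. An estimated correlation gave 7, 7, 7, 2 and 6 for manganese, alloy, alloy against iron, alloy against manganese and manganese against iron, in place of 11, 12, 12, 11 and 11, since it sets a correlation above the preset for each of those lists (0.0292 to 0.7003); fry, which tests another hypothesis, gave 22, 22, 19 and 22 for all but alloy against manganese, where it gave 10: it lost interferon-stimulated genes (adjusted p = 0.0875), integrated stress response (0.396), endoplasmic reticulum chaperones (0.215) and lysosome (0.215) and added heat shock proteins (0.00615), extracellular matrix (0.0322) and apoptosis regulators (0.00146). Alloy against manganese gave 7 to 13 lists leaving out 1 array (7 without alloy replicate 3). Reversed in alloy against manganese were metallothioneins (-0.0001 with median scaling), integrated stress response (-0.0231 with median scaling, -0.0548 with no normalisation, -0.0861 without alloy replicates 1, 3 and 4, 0.00 without alloy replicate 3), contractile genes (-0.0074 with no normalisation) and, without alloy replicates 1, 3 and 4, mitosis (0.17), endoplasmic reticulum chaperones (-0.0598), lysosome (-0.0856) and immediate early genes (-0.16), with lysosome in alloy against iron at -0.0013. Slc40a1 reversed for manganese, alloy, alloy against iron and manganese against iron to 0.64, 1.41, 1.32 and 0.54 in the non-normalized gene table, 0.15, 0.46, 0.44 and 0.13 in the normalized gene table and 0.18, 0.69, 0.64 and 0.12 as the mean of probes, its probes differing in sign. Apart from the minimum folds, the correlation, fry and Slc40a1, the cause was not tested. The iron counts of 311, 227 and 218 came from fits that left out alloy arrays. The fit with array weights (538) gave alloy replicate 3 the lowest weight (0.0955). Signal over background limits the arrays: 35.9% to 43.2% of probes lay above it.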

Other observations

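The test of the sum of the Tfrc changes below was chosen after the result was seen. Several lists that did not pass held genes moving both ways. So did all genes: of 13162, 3472 rose and 3733 fell with manganese (54.7% called), and 3560 rose and 3877 fell with the alloy (56.5%). Movement both ways thus does not by itself set these lists apart. Of 21 iron uptake, storage and export genes 7 rose and 7 fell with manganese and 8 rose and 5 fell with the alloy, Tfrc rising in both. Of 17 metallothioneins and zinc or manganese transporters 3 rose and 4 fell with manganese and 6 rose and 4 fell with the alloy, Mt1 falling in both. Of 27 p53 targets 12 rose and 8 fell with manganese and 13 rose and 8 fell with the alloy, Cdkn1a rising in both. Of 31 apoptosis regulators 6 rose and 12 fell with manganese and 8 rose and 16 fell with the alloy, where the list passed with no filter on dim probes (adjusted p = 0.0405). Of 41 respiratory chain genes 3 rose and 18 fell with manganese (median log2 change -0.12; adjusted p = 0.026 with no filter on dim probes) and 5 rose and 7 fell with the alloy (0.01). Medians of the other lists depended on the processing and the arrays, as that of p53 targets with the alloy, which went from 0.27 to 0.12 without alloy replicate 3 and to -0.04 without alloy replicates 1, 3 and 4.

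The alloy holds both metals, and iron lowered Tfrc while manganese raised it. The hypothesis that these changes add on the log2 scale was tested as alloy minus iron minus manganese plus control. The difference was -0.0783 (95% interval -0.33 to 0.18), with a sum of 0.84 against the alloy's 0.77. The Tfrc values are consistent with addition at these doses, which may hold by coincidence since the doses of manganese differ. Over all genes, 713 of 13162 differed from the sum.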
